A study of Mus musculus with 4 samples.

How the data were processed

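The series holds ATAC-seq of a mouse pancreatic cancer line, UN-KC-6141, with Ezh2 knocked out or with a control CRISPR plasmid. Per the labels' protocols, cells were transfected with knockout and homology-directed repair plasmids or the control plasmid and selected with puromycin, nuclei were tagmented with the Illumina Nextera kit, fragments of 200 to 500 bp were selected, and libraries were sequenced on a HiSeq4000. The labels name 4 libraries, EZH2 knockout replicates 1 and 3 and control replicates 3 and 4. Nothing in the labels says that they came from separate cultures.

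The authors deposited 1 annotated peak list per group. Each row gives a peak's chromosome, start, end and width, a score, an annotation class, the nearest transcript with its start, end and strand, the distance to its TSS, and gene names, per the file headers. Widths equal the end minus the start plus 1 in all 244970 control and 199440 knockout peaks, so positions were read as 1-based. The genome build is mm10 per the submitters' processing notes. The aligner, the peak caller, any shift of reads for the transposase offset, the removal of duplicates and the way the 2 libraries of a group were joined are not given in the sources used here. The deposited score values are the authors' own value for each peak, and their unit and normalization are not stated. The lowest score was 0.0337 in the control list and 0.0370 in the knockout list. Scores were therefore used to describe, rank or filter peaks within a list, and no ratio of scores between lists was formed. The exception was the setting with a score above the control list's median, which put the same threshold on both lists. Each list may depend on its depth and threshold, which shift the number of weak peaks. Depth per library was unknown, so no counting interval was given. The files hold no counts per library, so the planned test of differential peaks and the leaving out of single libraries were not run.

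Peaks of the lists were compared by an overlap of at least 1 bp. Chance overlap was estimated by shifting all control peaks of a chromosome by a common random distance, wrapped at the ends, 100 times. A promoter was called open when a peak lay within 1000 bp of the TSS of its nearest gene by the distance in the files. Gene lists were fixed before the data were examined, 23 in all: PRC2 and PRC1 subunits and H3K27 demethylases, Hox genes, other developmental transcription factors, cell cycle inhibitors and senescence, NRF2 targets, macropinocytosis, autophagy and lysosome, NF-kB pathway, RAS and MAPK feedback, epithelial adhesion and keratins, mesenchymal genes, markers of ductal, acinar, islet, immune, fibroblast, endothelial and neural cells, germline genes, antigen presentation and interferon, Wnt pathway, imprinted genes and housekeeping genes. For each list, the knockout-only minus the control-only members were set as a percentile among 10000 random lists of the same size, matched on 10 classes of the number of peaks assigned to a gene. Matching on CpG content was not possible because no genome sequence was used here. These percentiles describe the 2 lists and are not p-values. Genes that the files never name were left out of a list's size.

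For promoters open in both lists, the highest promoter score of a gene was ranked within each list over the same 12820 genes. The median shift of a gene list, relative to the chromosome's median, was set against 10000 random lists matched on 10 classes of mean rank. The genes named were fixed by a rule before the data were examined: Ezh2, Ezh1, Eed, Suz12, Cdkn2a, Chuk and Kras always; up to 4 members of each list open in a single list, by score, taking the direction with more members first; and the 10 strongest promoters in each direction with no peak of the other list assigned to the gene within 5 kb, leaving predicted genes, microRNAs, snoRNAs and olfactory and vomeronasal receptors unnamed. Genes named outside the rule are said to have been chosen after their values were seen.

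The alternatives fixed beforehand were promoters of 500 and 3000 bp, the promoter class of the files, equal numbers of top peaks, a score above the control list's median or above 2 times the list's lowest (asked of the peaks counted, while all peaks of the other list were kept), autosomes only, and overlaps of 50%. Added after the data were seen were peaks assigned to every TSS within 1000 bp, the 20000 highest-scoring peaks of each list, leaving out chromosomes whose ratio of control to knockout peaks lay over 1.5 times from the median, random lists drawn from protein-coding genes of the reference gene table (assembly GRCm38.p6), random lists matched on the chromosome as well as the number of peaks, and the settings of the rank comparison. Correlation across chromosomes was tested with 100000 permutations, two-sided.

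The overlap code was tested on planted overlaps, of which 100.0% were recovered over 244821 peaks, and gave the same counts as bedtools 2.31.1. Of 1000 random lists of 25 genes drawn from 22261, 5.0% fell outside the central 95%, and all of 200 lists with 8 planted control-only members were recovered. The other members of these planted lists were open in both lists, so the recovery of smaller excesses was not tested. For the rank shift, 4.4% of 1000 random lists of 25 shared promoters fell outside, and 66.0% of 50 lists of 15 promoters moved up by 15 rank points were recovered, so a shift of that size in a list of 15 genes could be missed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.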

Results

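Accessible chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA. The cells were UN-KC-6141, a mouse pancreatic ductal adenocarcinoma line that the labels trace to tumours carrying an oncogenic Kras allele and lacking Ikkα (encoded by Chuk) in pancreatic epithelium. The 2 groups were cells in which Ezh2 had been knocked out with CRISPR/Cas9 and cells that had received a control CRISPR plasmid. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which places a repressive methyl mark on histone H3. There were 4 libraries, 2 per group. The deposited data were 1 peak list per group, with a score for each peak and no values per library. No difference below therefore had a replicate check, and no p-value was computed across genes. The sequencing depth was unknown.

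The first comparison concerned the size and make-up of the lists. The control list held 244970 peaks and the EZH2 knockout list 199440, covering 59.9 Mb and 60.7 Mb. Peaks in the control list were narrower, with a median width of 174 bp against 199 bp. Promoter peaks, within 1000 bp of a transcription start site (TSS), numbered 23564 in the control list (9.62%) and 22420 in the knockout list (11.2%). More of the control list lay close to its lowest score: 12.3% of control peaks and 28.1% of knockout peaks scored more than 2 times the lowest value of their own list.

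Chromosomes 3 and 6 were rich in control peaks, and chromosomes 4 and X were poor in them. Chromosome 6 held 195 control peaks per Mb against 72.4 in the knockout list, and chromosome 3 held 156 against 73.6. On chromosome 4 the order turned, with 43.2 control and 79.6 knockout peaks per Mb, and on chromosome X the values were 6.70 and 19.3. Across the 19 autosomes the density ranged from 43.2 to 195 peaks per Mb in the control list and from 70.1 to 93.3 in the knockout list. The ratio of control to knockout peaks had a median of 1.15 over the 20 chromosomes. Only chromosomes 3, 4, 6 and X lay more than 1.5 times away from that median, and results on genes were also computed without these 4 chromosomes.

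**Figure D1:**
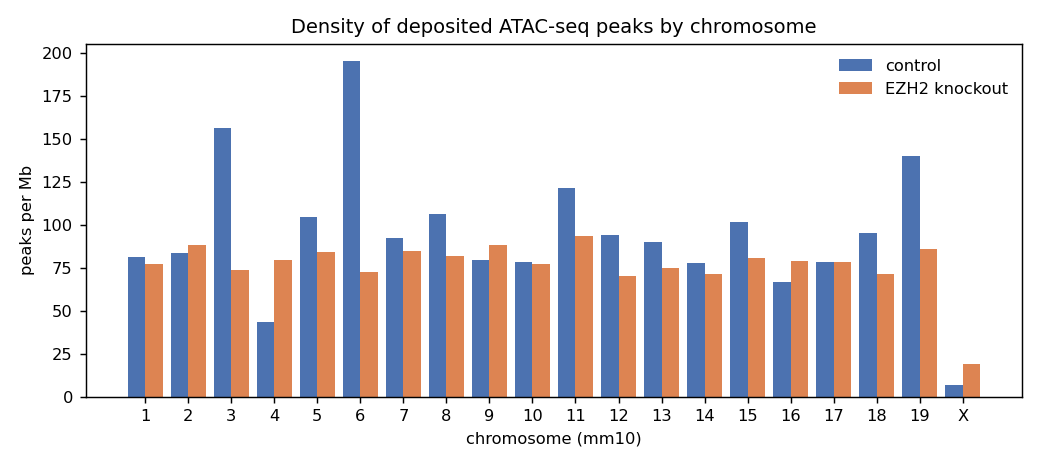
Deposited peaks per Mb (vertical axis) on each mouse chromosome (horizontal axis), with a bar for the control list and a bar for the EZH2 knockout list. Control bars stand at 195 on chromosome 6 and 43.2 on chromosome 4, while knockout bars on the autosomes stay between 70.1 and 93.3.

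The second comparison asked which peaks the lines shared. The strongest peaks of each list were found in the other list, and most weak peaks were not. All of the 1000 highest-scoring peaks of each list overlapped a peak of the other by at least 1 bp. Over the whole lists, 57329 control peaks (23.4%) and 55647 knockout peaks (27.9%) were shared. After the control peaks had been shifted along their chromosomes 100 times, the shares were 4.35% ± 0.0809 and 5.26% ± 0.0945 (SD over shifts). Among the peaks ranked below 100000, 9.83% of control and 9.45% of knockout peaks were shared.

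Shared peaks lay at promoters far more often than peaks found in 1 list. Promoters held 27.4% of the shared peaks of either list, 4.18% of control-only peaks and 4.997% of knockout-only peaks. Introns and distal intergenic DNA held 41.1% and 45.2% of control-only peaks, and 42.5% and 44.5% of knockout-only peaks. The median distance to the nearest TSS was 29988 bp for control-only and 28017 bp for knockout-only peaks, against 9543 bp for shared control peaks and 9668 bp for shared knockout peaks. In the knockout list, strong peaks without a control counterpart were mainly distal. Of 3933 promoter peaks that scored above 0.5 there, 10 (0.254%) had no control peak, against 157 of 2045 other peaks (7.68%). In the control list the share without a counterpart was also lower at promoters. Above 0.5, 2 of 2396 promoter peaks (0.0835%) and 2 of 244 other control peaks (0.820%) had no knockout peak. Between 0.2 and 0.5, the values were 10 of 3958 (0.253%) and 73 of 2087 (3.50%). The strongest knockout peak without a control counterpart, of score 1.09, lay in intergenic DNA on chromosome 5 (48330859 to 48331964). Its nearest gene was Pacrgl. The strongest control peak without a knockout counterpart, of score 0.833, overlapped a TSS of Prkcz on chromosome 4 (155360750 to 155362188). Both peaks were chosen after their values were seen. Coordinates are those of mouse build mm10.

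The targeted gene was accessible at its promoter in both groups. The Ezh2 promoter peak (Entrez 14056) lay on chromosome 6 at 47594084 to 47595937 in the control list, with rank 1261 of all peaks, and at 47594086 to 47595604 in the knockout list, with rank 3912. An accessible promoter does not test whether the coding sequence was edited, so these peaks do not check the labels. Ezh1, Eed and Suz12, which encode the related methyltransferase and the core partners of EZH2, also had promoter peaks in both lists, as did Chuk and Kras. Of 26 genes for PRC2 and PRC1 subunits and H3K27 demethylases, 25 had a promoter peak in both lists and none in a single list. Cdkn2a, which encodes the cell cycle inhibitors p16 and ARF and is a known Polycomb target, had a promoter peak in neither list. Its nearest assigned peaks were 24049 bp from the TSS in the control list and 23968 bp in the knockout list. Missing peaks alone do not tell a closed promoter from lost DNA, and no DNA input was used here.

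The third comparison, which follows the title of the series, asked which promoters were open in 1 list only. E-cadherin, its regulators and keratins were among the genes open only in the control list, and no gene of that group was open only in the knockout list. Over 22261 named genes, 12820 had a promoter peak in both lists, 2223 in the control list only and 1807 in the knockout list only. Most of these single-list promoters were weak. A score above 2 times the list's lowest value was reached by 242 control-only genes (10.9%) and 508 knockout-only genes (28.1%). With peaks assigned to any TSS within 1000 bp in place of the nearest gene of the files, the counts were 1940 and 1548.

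Of 25 genes for epithelial adhesion and keratins, 15 were open in both lists, 8 in the control list only and 0 in the knockout list only. The excess of knockout-only over control-only members, -8, lay at percentile 0.01 of 10000 random gene lists matched on the number of peaks per gene. Cdh1 (Entrez 12550), which encodes E-cadherin, had the strongest of these promoters, a control peak of score 0.152 and rank 11683 on chromosome 8 (106602975 to 106603756) that overlapped the TSS. The nearest knockout peak assigned to Cdh1 lay 8763 bp downstream, in intron 2. Grhl2 and Ovol1, epithelial transcription factors, had control peaks of score 0.0710 and 0.0734, and Cldn7, a tight junction claudin, one of 0.0519. The nearest knockout peaks assigned to Grhl2 and Ovol1 lay 1293 and 1962 bp from the TSS. The other 4 were Krt5, Krt7, Krt14 and Krt17, with control scores from 0.0354 to 0.0489, and were chosen after their values were seen. Krt5 and Krt7 lie near each other on chromosome 15, and Krt14 and Krt17 on chromosome 11. Random lists drew genes independently, so the percentile may be too extreme. The percentile stayed below 2.5 under each of the 11 alternative settings, the highest being 1.995 with promoters of 3000 bp. The promoter class of the files held the same peaks as the main definition, so it was no separate check. Random lists of protein-coding genes or matched on chromosome could change only the percentile, not the excess.

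**Figure D2:**
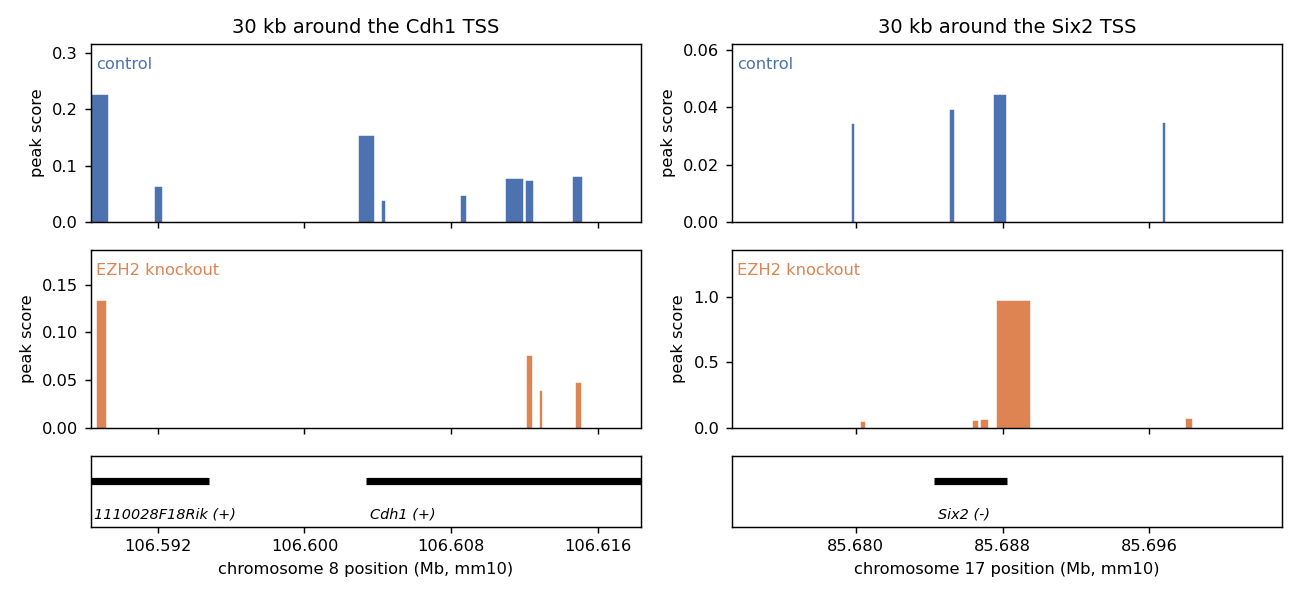
Deposited peaks around the TSS of Cdh1 (left) and Six2 (right), each drawn from start to end on the horizontal axis (Mb, mm10) with its score as height, and gene spans below. The control list has a peak of score 0.152 at the Cdh1 TSS and the knockout list none, and the Six2 promoter peak scores 0.0443 in the control and 0.971 in the knockout list; each panel has its own score axis.

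Developmental transcription factors outside the Hox clusters, a class of genes that PRC2 typically represses, were more often open in the control list alone, but mostly by weak peaks. Of 119 such genes, 79 were open in both lists, 24 in the control list only and 7 in the knockout list only (percentile 0.09). The strongest control-only promoters were those of Evx1 (score 0.104), Tbx2 (0.0888), Zic2 (0.0857) and Sox1 (0.0695), and Tbx2 and Zic2 did have a knockout peak within 1000 bp of a TSS that the files assign to another gene. The nearest knockout peak assigned to Sox1 lay 1011 bp from its TSS, just outside the promoter limit. Of these single-list genes, 4 control-only and 3 knockout-only ones had a peak above 2 times the lowest score of their list (percentile 12.5). The 3 knockout-only ones were Irx5 (1.53), Foxg1 (1.30) and Gata6 (0.476), Irx5 being named after its values were seen. Each of them likewise had a control peak within 1000 bp of a TSS by coordinates. With only the 20000 highest-scoring peaks of each list the direction turned, with 6 control-only and 15 knockout-only genes (percentile 100).

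Islet markers, 7 control-only and 2 knockout-only of 25 (percentile 1.92), were the third list outside the central 95%; among the control-only members were Neurod1 and Pax4 with scores of 0.0427 and 0.0422, and that call was lost in 7 of the 11 alternative settings. For 23 lists, 1.15 would fall outside by chance. The other 20 lists had percentiles from 3.93 to 93.1. Immune markers had 7 control-only and 3 knockout-only genes of 21, with 3 open in both lists, fibroblast markers 0 and 2 of 14, neural markers 0 and 1 of 20, and endothelial markers 0 and 0 of 13. Acinar markers had 4 and 5 of 20, with 6 open in both lists, and ductal markers 0 and 1 of 17. The knockout-only call of the trypsinogen gene Prss2 (score 0.301) rested on the promoter limit, since its peak lay 1000 bp from the TSS and overlapped a control peak, and the nearest control peak assigned to the gene lay 1148 bp away. Among 21 mesenchymal genes, Sparc (0.442) and Tagln (0.138) had a promoter peak in the knockout list only and Mmp2 (0.0421) in the control list only. Hox genes counted 5 and 2 of 38, imprinted genes 5 and 1 of 22, germline genes 4 and 4 of 18, and Wnt pathway genes 3 and 2 of 29. Antigen presentation and interferon genes counted 2 and 2 of 24, with Isg15 open only in the knockout list at a score of 0.2496. NRF2 targets and autophagy and lysosome genes each had 1 in either direction, of 24 and 32 genes, while macropinocytosis (Wnt3a, of 23) and housekeeping genes (Snrpd3, of 26) each had 1 knockout-only member. All 18 NF-kB pathway genes and all 20 RAS and MAPK feedback genes were open in both lists, as were 13 of 15 cell cycle inhibitor and senescence genes, the other 2 being open in neither.

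**Figure D3:**
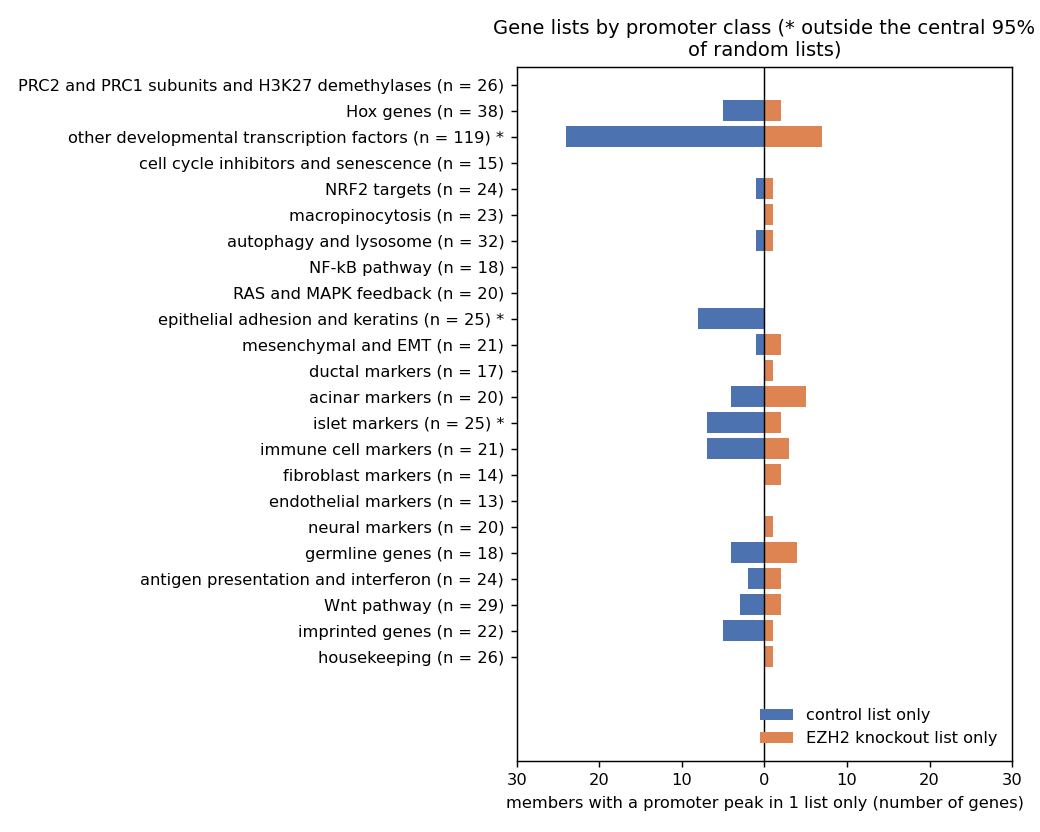
Number of genes (horizontal axis) in each list fixed beforehand whose promoter held a peak in the control list only (left of 0) or the EZH2 knockout list only (right of 0). Epithelial adhesion genes and keratins reach 8 on the control side and 0 on the knockout side; asterisks mark the 3 lists outside the central 95% of random lists.

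Over all genes, the strongest knockout-only promoters of genes with no assigned control peak within 5 kb included Mospd2 (score 1.73), Foxg1 (1.30), Hccs (1.03), Pate1 (0.855), Pdzd11 (0.680) and Gata6 (0.476). The strongest control-only promoters included Snhg10 (2.19), Fancb (0.711), Slc13a1 (0.688), Particl (0.628) and Stpg2 (0.455). In each direction 7 of the 10 strongest genes had a peak of the other list at a TSS by coordinates, because the files assign each peak to a single nearest gene. The genes left without such a peak were Pate1, Cavin4 and Ctla2a in the knockout list, and Slc13a1 (a sulfate transporter), Stpg2 and Ifi27l2b in the control list. Next in the control list by score came Lbp, the lipopolysaccharide-binding protein (0.247), and the xenobiotic-metabolising enzymes Ugt2b34 (0.205) and Cyp3a13 (0.190), named after their values were seen.

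The last comparison ranked the 12820 promoters open in both lists by their peak score within each list, from 0 to 100, so that both rankings ran over the same genes. Promoters of developmental transcription factors and mesenchymal genes ranked higher in the knockout list, and those of epithelial genes lower. Shifts were taken relative to the median shift of the gene's chromosome. The 79 shared developmental transcription factors had a median shift of 7.39 rank points, outside the central 95% of random lists matched on rank (-3.64 to 3.36, percentile 99.99), with 56 higher and 23 lower. Six2 (Entrez 20472), a regulator of nephron progenitors, went from rank 8.07 in the control to 90.5 in the knockout list, and its knockout promoter peak lay on chromosome 17 at 85687694 to 85689420. Sox11 went from 11.1 to 65.6, Zic3 from 10.2 to 64.95, Msx2 from 16.3 to 59.7 and Pax3 from 10.6 to 52.8. Among those that went the other way were the endoderm factors Foxa2, from 81.7 to 37.8, and Cdx2, from 50.8 to 22.6. Genes named here by rank were chosen after their values were seen.

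The 15 shared epithelial promoters had a median shift of -16.5 rank points (percentile 0.02), and 14 of them ranked lower in the knockout list. Elf3, an epithelial transcription factor, went from rank 83.1 to 14.0, the adhesion gene Epcam from 26.5 to 2.34, and Krt19, a ductal keratin, from 60.3 to 20.4. The 17 shared mesenchymal promoters had a median shift of 12.7 (percentile 99.28), with 14 higher, among them Twist1 from 17.7 to 60.4, Zeb2 from 24.8 to 52.4 and Vim from 51.5 to 72.3. Zeb1, also a repressor of epithelial genes, went from 40.1 to 17.7. These 3 lists stayed outside the central 95% in all 5 alternative settings. Of 21 lists with at least 5 shared genes, 6 lay outside, where 1.05 would by chance. The other 3 were Hox genes (31 promoters, shift 7.03, percentile 99.19), fibroblast markers (5 promoters, 24.5, percentile 99.63) and macropinocytosis genes (20 promoters, -9.51, percentile 1.91). Hoxc13 went from rank 14.8 to 78.6. The Hox call rested on the chromosome adjustment, without which the median shift was -0.218, and the Hox genes lie in clusters and are not independent. The remaining 15 lists had percentiles from 3.76 to 91.9. This test of lists by rank was chosen after the data were examined.

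**Figure D4:**
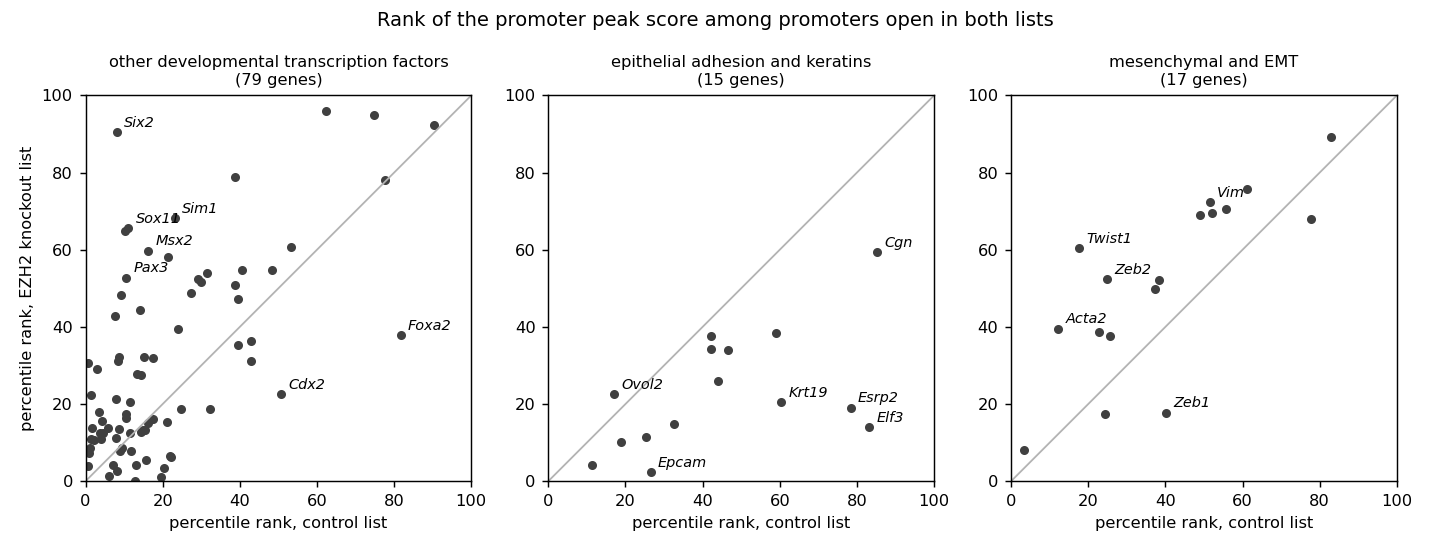
Percentile rank of the promoter peak score in the control list (horizontal axis) and in the EZH2 knockout list (vertical axis) among promoters open in both, with a point for each gene of 3 lists and a line of equal rank. Six2 stands at 8.07 and 90.5 above the line, Elf3 at 83.1 and 14.0 below it, and 14 of 15 epithelial genes lie below and 14 of 17 mesenchymal genes above after the chromosome adjustment.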

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

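Settings chosen after the data were seen were those with peaks assigned by coordinates, the top 20000 peaks, without 4 deviating chromosomes, random lists of protein-coding genes or matched on chromosome, and all settings of the rank comparison. The cause of a change was not tested unless the setting itself removes peaks. The excess of epithelial members, main value -8, ranged from -9 to -3 over 11 alternatives and moved to -5 with promoters of 3000 bp and to -3 above 2 times the lowest score, always below percentile 2.5. The excess of developmental transcription factors, -17, was -9 with promoters of 500 bp (percentile 4.75), -12 with 3000 bp, -6 with equal numbers of top peaks (percentile 8.85), -10 above the control median score (percentile 0.255) and -1 above 2 times the lowest score (percentile 12.5), and it reversed to 9 with the top 20000 peaks. The excess of islet markers, -5, was 0 with 3000 bp, -1 above the control median score, and reversed to 1 both above 2 times the lowest score and with the top 20000 peaks. The median rank shift of Hox genes, 7.03, reversed to -0.218 with no chromosome adjustment, and that of macropinocytosis genes, -9.51, was -8.48 without the deviating chromosomes (percentile 4.23). The rank shifts of developmental, epithelial, mesenchymal and fibroblast genes kept their direction and their side of the threshold in each alternative run.

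Counts and shares moved with the score threshold, which was asked of the list counted while the other list kept all its peaks. Above 2 times the lowest score were 56067 knockout and 30027 control peaks, of which 64.5% and 86.2% overlapped any peak of the other list, and 508 knockout-only and 242 control-only genes. Above the control median score were 122485 control peaks and 1241 control-only genes, with 37.0% of knockout and 37.6% of control peaks shared. With only the top 20000 peaks of both lists, 679 genes were knockout-only and 1796 control-only, and 63.2% of knockout and 63.9% of control peaks were shared. That order of genes is the one of the main result (1807 knockout-only and 2223 control-only) and the opposite of that above 2 times the lowest score. Equal numbers of top peaks gave 26.5% and 27.1% shared, with promoters holding 28.3% of shared knockout, 28.3% of shared control and 4.35% of control-only peaks. An overlap of 50% of the shorter peak gave 25.7% and 21.5%, a reciprocal overlap of 50% gave 15.7% and 12.8%, and leaving out the deviating chromosomes gave 27.5% and 25.02%. Over these results, 67 values under alternatives were called the same (counts within 1.5 times, shares within their 95% Wilson interval, list excesses within 1 SD of random lists, rank shifts on the same side of the threshold), 33 moved, 4 reversed and 1 weakened; over the others, 264 were the same, 27 moved and 2 rank shifts passed the threshold. These tallies include the promoter class of the files, which repeats the main definition. They also include the settings of other random lists, which leave a list's excess unchanged or nearly so. For the 20 lists whose excess lay inside the central 95%, 7 of 220 values under alternatives lay outside it, in Hox, mesenchymal, fibroblast and imprinted genes.

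No paired analysis was possible because the groups share only replicate number 3 and the lists carry no values per library. For the same reason no library was left out, and the planned differential test with its normalizations and filters was not run. The depth was unknown, so what it limits was not tested.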

Other observations

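Several loci stood out beyond the gene groups described. Cdkn2a and Cdkn2b lie in a stretch of chromosome 4 with no peak in either list, from 89258225 to 89348853 (90.6 kb). Whether that DNA was present in the cells was not tested. The promoter of Tgfa, which encodes a ligand of the EGF receptor, went from rank 82.0 in the control to 18.2 in the knockout list, and that of the receptor gene Egfr from 21.0 to 50.5. The imprinted genes Peg3 and Ndn went from rank 0.523 to 39.4 and from 4.12 to 37.2, while Slc22a18 went from 54.0 to 2.12; of 14 shared imprinted genes, 5 ranked higher and 9 lower relative to the chromosome (median shift -7.21, percentile 3.76). The fibroblast genes Pdgfra and Pdgfrb went from 34.9 to 58.8 and from 4.91 to 31.1. These genes were chosen after their values were seen.

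The tests chosen only after the result was seen were both tests of chromosome density, the reading of the score threshold for developmental genes (the threshold itself was fixed beforehand), all tests of ranks, the test of epithelial genes matched on chromosome, and both tests of endoderm genes. The uneven density of control peaks was weighed first. For chromosomes the rank shift was the control minus the knockout rank, the reverse of the direction used for gene lists. Across the 20 chromosomes, the log2 ratio of control to knockout peaks rose with this median shift of shared promoters. Pearson r was 0.898 (p = 1e-05, the smallest that 100000 permutations can give) and Spearman rho 0.722 (permutation p = 0.0004). Benjamini-Hochberg adjusted over the pair, the values were 2e-05 and 0.0004. Without chromosomes X and 6, r was 0.803 and rho 0.618. Chromosomes with relatively more control peaks thus had shared promoters of higher rank in the control list. A threshold or depth acting alike on all autosomes would leave their ratios nearly equal, and with all peaks counted the highest was 4.98 times the lowest. The contrast between the extreme autosomes was smaller among stronger peaks. Above 2 times the lowest score, chromosome 6 held 2502 control and 3036 knockout peaks, and chromosome 4 held 1254 and 3401. What part of the spread the threshold made was not tested. A difference in DNA copy number between the lines is a candidate explanation, but it could not be separated from a difference in chromatin over whole chromosomes, since no DNA input was used here.

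The second pattern was the opposite direction of developmental transcription factors by presence and by rank. Whether the longer tail of weak control peaks accounts for the control-only excess could not be decided. The excess lay inside random lists (percentile 12.5) once single-list genes had to score above 2 times the lowest score of their list. All peaks of the other list were kept. But the knockout-only genes then left, Irx5, Foxg1 and Gata6, each had a control peak at a TSS by coordinates. Likewise, the control-only Tbx2 and Zic2 had a knockout peak at a TSS by coordinates, and Sox1 had one 1011 bp from its TSS. For the lowest-scoring peaks the settings differed. Above the control median score the control-only excess stayed outside (percentile 0.255). With equal numbers of top peaks, which drops only the weakest control peaks, it was -6 and lay inside (percentile 8.85). Assignment of the same promoter peak to different genes did not account for the rank shift, which lay at percentile 100 with peaks assigned by coordinates. What raised the ranks of shared developmental promoters was not tested: each group has a single peak list, and the labels do not say whether its libraries came from 1 clone or culture, so an effect of EZH2 and a difference between selected populations stay open.

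The third pattern was the loss of peaks at epithelial promoters in the knockout list. DNA copy number of whole chromosomes differing between the lines did not account for it (percentile 0.04 of random lists matched on chromosome), while copy number of smaller segments was not tested. Neighbouring keratin genes counted as independent members in that percentile. Low-scoring background peaks of the longer control list did not account for the excess left above 2 times the list's lowest score (percentile 0.03). Of the 8 control-only genes, only Cdh1, Grhl2 and Ovol1 reached that score. Knockout peaks assigned to Grhl2 and Ovol1 lay 1293 and 1962 bp from the TSS. The calls of Grhl2 and Ovol1 therefore do not hold with promoters of 3000 bp. For Cldn7 and the control-only keratins, background peaks stay open. Lower accessibility across the epithelial promoters, shared ones included, went with percentile 0.02, while mesenchymal promoters ranked higher (percentile 99.25 to 99.7 over alternatives), except 3 of 17 with Zeb1 among them, as did fibroblast markers (median shift 24.5, percentile 99.63). The fibroblast shift rested on 5 promoters, and 7 of 14 fibroblast markers were open in neither list. Ductal markers did not shift down: their median shift was 5.0, inside random lists (percentile 81.9), with 8 of 12 shared promoters higher. Without the chromosome adjustment their median shift was 1.44, and the median rank of the list went from 41.5 in the control to 33.1 in the knockout list. A hypothesis is that the knockout line may have moved from an epithelial towards a mesenchymal or fibroblast-like chromatin state. Which of these it was, and whether it followed from the loss of EZH2 or from the outgrowth of different cells during selection was not tested.

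A further hypothesis, prompted by Lbp, Ugt2b34 and Cyp3a13 among the strongest control-only promoters, was that a wider endoderm epithelium programme may be lost. Of 35 such genes listed after those were seen, 5 were control-only and 2 knockout-only, at percentile 17.75, which leaves it open. Of the 11 open in both lists, 10 ranked lower in the knockout list, with a median shift of -15.7 relative to the chromosome; this lower accessibility of endoderm promoters open in both lists lay at percentile 0.05, in a test chosen once their ranks had been seen. Hnf4a went from rank 60.2 to 5.02 and Hnf1a from 17.3 to 1.05, and Apob alone ranked higher.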
